A study of Homo sapiens with 4 samples.

How the data were processed

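Full-length cDNA of cells labelled Huh7 was sequenced as PacBio Iso-Seq long reads in 4 libraries, 2 transfected with a negative control siRNA (siNC) and 2 with an siRNA against STAMBPL1 (siSTAMBPL1). The labels name lipofectamine as the transfection reagent, a SMART PCR cDNA synthesis kit and a SMRTbell template preparation kit. The genome build was hg38, per the submitters' processing notes. The aligner, the transcript caller, the event caller and the number of reads are not given in the sources used here.

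Each deposited file is a list of alternative splicing events of 1 library. Per the file headers, an event has a gene identifier, an event identifier with its type and exon coordinates, the transcripts that carry its first form and the transcripts that carry either form. The 7 types are alternative first exon, alternative last exon, skipped exon, alternative 3' splice site, alternative 5' splice site, retained intron and mutually exclusive exons. Transcripts are Ensembl transcripts or transcripts with identifiers that begin with PB, called PB or long-read transcripts here. Ensembl transcripts on a list can have been found in the long reads too. A gene without PB transcripts may therefore still have been detected. The files the authors deposited hold no read number, percent spliced in or other quantity, so an event is either listed in a library or not. No test of single events was made for that reason, as fixed for such a file before the data were examined. A gene level test on counts of reads was not possible either, and the number of distinct events per gene was tested with limma in its place. A number of events is not a level of expression: a single added transcript that differs from the others in several exons can add many events.

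What puts an event on a list was tested on the files. The Ensembl transcripts of an event were identical in every library that listed it, with 0 mismatches. Every event without a PB transcript held at least 1 Ensembl transcript that occurred in no missing reference-defined event of that library, with 0 exceptions in each library. An event was thus taken as listed when at least 1 transcript of either form had been found in the library. Read numbers not being given, PB transcripts stand here in place of a measure of depth. Knockdown could itself change the number of PB transcripts, so that number is not depth alone. They differed: PB transcripts numbered 32307 and 32750 in siNC replicates 1 and 2, and 25463 and 17584 in siSTAMBPL1 replicates 1 and 2. Fewer transcripts leave fewer events to list. To compare libraries at equal numbers of PB transcripts, which does not equalise reads, the PB transcripts of each library were drawn at random down to 17584. The events that still held a PB transcript were counted. Shares of types are means over 20 seeded draws. The ratio of events, the sharing of events and the gene and list fits used a single draw, so their spread over draws was not measured.

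The files give Ensembl gene identifiers without symbols. Symbols were assigned by position, from the RefSeq gene table of GRCh38.p14, the assembly of hg38. A gene was matched where at least 60% of its event positions lay within 50 bases of a RefSeq gene, at least 20% of that gene's span was covered, and the best match scored at least 1.5 times the next. Of 11931 Ensembl genes with an event, 10616 (89.0%) received 1 symbol, 240 overlapped several RefSeq genes and 975 had no candidate. Strand was not used, so names of genes that overlap on opposite strands are less certain. Of 1103 genes on the fixed lists, 901 were matched to a gene with an event.

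Numbers of events and shares of types were compared by an exact two-sided permutation test, with Benjamini-Hochberg adjustment over types. With 2 libraries against 2, the smallest p is 0.333. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Events were matched between libraries by gene, type and every coordinate. At the gene level, the number of events was divided by the library total relative to the mean total, a pseudocount of 1 was added, and log2 values were fitted with limma (lmFit, eBayes with trend) for the 9933 genes with at least 5 events over the 4 libraries. Log2 changes are therefore on the log2(scaled events + 1) scale, which understates changes of genes with few events. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it, for lists with at least 5 tested genes. Benjamini-Hochberg adjustment was applied at a threshold of 0.05. The median of each list was also set among 10000 random lists matched on mean level.

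The fit was tested on simulated data with 200 changed genes, drawn from the real means and library totals with the mean dispersion of the real libraries (0.0704), over 9804 genes for the comparison of siSTAMBPL1 with siNC. It passed 1 of 50 genes changed 2-fold, 11 of 50 changed 4-fold, 36 of 50 changed 8-fold and 36 of 50 changed 16-fold. No unchanged gene passed. The simulation gives every gene the same dispersion and leaves out the jumps between 0 and many events seen in the real libraries. Changed genes were drawn only from those with a mean of at least 5 events per library. Recovery of genes with fewer events, such as STAMBPL1 with 11 over all libraries, was not measured.

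The rule for named genes was fixed before the data were examined: STAMBPL1 and STAMBP, then 12 genes per direction with the largest log2 change. Genes past the threshold came first. The rest were filled from genes with at least 20 events for which both siSTAMBPL1 libraries lay beyond both siNC libraries. From presence, the 10 genes per direction with the most group-specific events were named, and from each list up to 4 tested members with the smallest p. Where a member of a list is given, those of the list with a smaller p are given too, but how many are given per list (0 to 4) was chosen after the values were seen. Genes without a symbol were skipped. 2 genes that the rule would name are not reported here. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

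Alternatives fixed in advance were the unit counted, the genes, chromosomes and events kept, the tolerance of coordinates, thinning of events, the pseudocount, the filter, the scaling, the trend, the replicate number as a block, the list test, and each library left out. Alternatives with PB transcripts, events with both forms seen, events with Ensembl transcripts in both forms and events without first or last exons were added after the data were seen. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.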

Results

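The series asked how the transcripts of cells labelled Huh7, a line of hepatocellular carcinoma, differed after knockdown of STAMBPL1. STAMBPL1 is a deubiquitinase related to STAMBP, an enzyme of endosomal sorting. Long-read sequencing gave 4 lists of alternative splicing events, from 2 siNC and 2 siSTAMBPL1 libraries. The lists held 140317 and 142215 events in siNC replicates 1 and 2, and 119505 and 94432 events in siSTAMBPL1 replicates 1 and 2. The events fell in 10421, 10523, 9976 and 9107 genes, in the same order of libraries. Values for the 4 libraries are given in that order throughout. An event was present or absent on a list, with no quantity attached.

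The targeted gene was examined first. STAMBPL1 (ENSG00000138134, RefSeq span chromosome 10, 88880245 to 88923487, hg38) had 3 and 6 events in the siNC libraries and 1 and 1 in the siSTAMBPL1 libraries. PB transcripts in its events numbered 1 and 4 in siNC and 0 and 0 in siSTAMBPL1. The event left in both siSTAMBPL1 libraries was an alternative last exon that held Ensembl transcripts only, with coordinates from 88922436 to 88975153, which extend past the RefSeq end of the gene. On the log2 scale the change was -1.14 ± 0.470 (SE, n = 2 against 2), with a limma adjusted p of 0.743. Both siSTAMBPL1 libraries thus lay below both siNC libraries, but the difference did not pass the test, and it rests on few events. STAMBP (ENSG00000124356) had 12, 10, 8 and 9 events, a log2 change of 0.04 ± 0.319 (SE) with a limma adjusted p of 0.981. PB transcripts in STAMBP events numbered 4, 2, 0 and 2. Among events with a PB transcript the log2 change was -1.19 for STAMBP and -1.91 for STAMBPL1, and neither passed. A fall particular to STAMBPL1 is thus not shown.

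**Figure D1:**
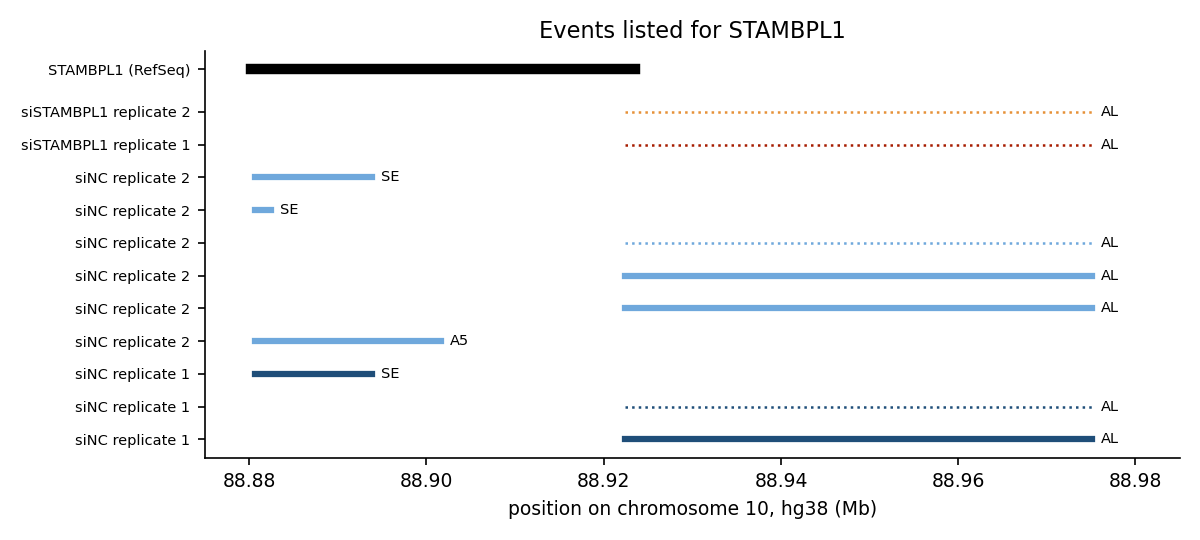
Events listed for STAMBPL1 along chromosome 10 (hg38, Mb), 1 line per event and library from its first to its last coordinate, with the type at the right end (SE skipped exon, A5 alternative 5' splice site, AL alternative last exon). Solid lines held a PB transcript and dotted lines held Ensembl transcripts only. The siNC libraries had 3 and 6 events and the siSTAMBPL1 libraries 1 each.

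Fewer events were listed after knockdown in all 7 types. The siNC libraries averaged 141266 ± 1342 events (SD, n = 2) and the siSTAMBPL1 libraries 106969 ± 17729 (SD, n = 2), a ratio of 0.757. The exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 allow. Alternative first exons numbered 57784 ± 857 in siNC and 40939 ± 8439 in siSTAMBPL1 (SD, n = 2 each). Skipped exons numbered 33151 ± 224 and 27421 ± 2920, and retained introns 10317 ± 106 and 7332 ± 1445. The number of long-read transcripts had a lower ratio than the number of events, 0.662, and the number of genes with an event a higher one, 0.911. For events with a PB transcript the ratio was 0.7052. After thinning of PB transcripts to an equal number, that ratio was 0.995 in a single draw. At equal numbers of transcripts a ratio near 1 is largely built in.

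**Figure D2:**
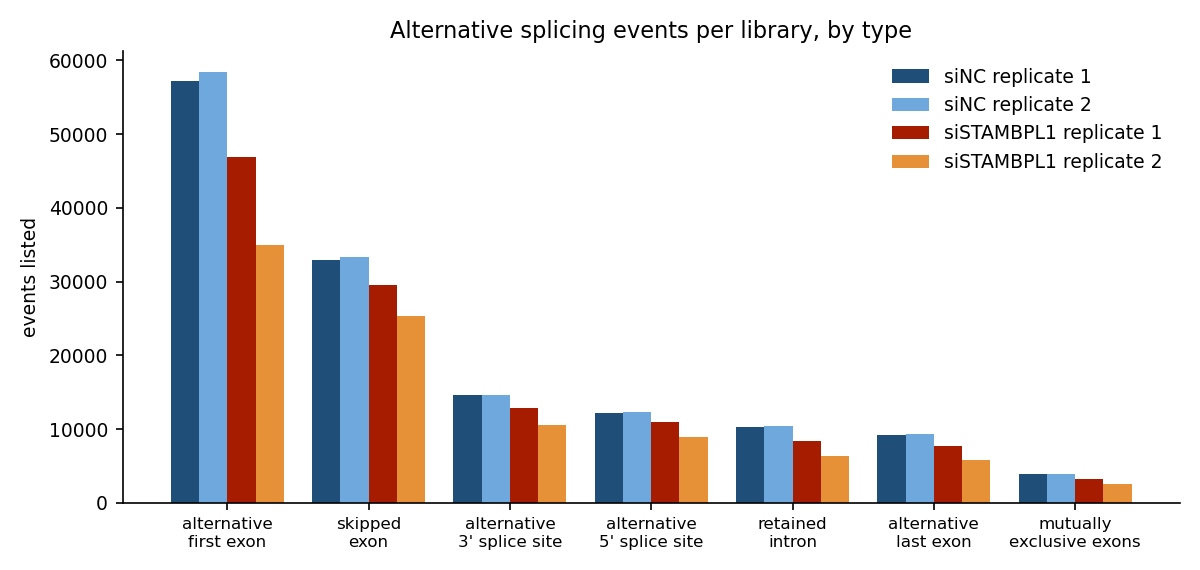
Number of alternative splicing events listed per library (vertical axis) for each of the 7 event types, with 1 bar per library. For skipped exons the bars stand at 32992 and 33309 in siNC and at 29486 and 25356 in siSTAMBPL1.

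The mix of event types differed between the groups as well. Alternative first exons made up 40.7% (95% interval 40.5 to 41.0) and 41.1% (40.8 to 41.3) of events in siNC, and 39.3% (39.0 to 39.5) and 37.0% (36.7 to 37.3) in siSTAMBPL1. Skipped exons made up 23.5% and 23.4% in siNC and 24.7% and 26.9% in siSTAMBPL1. Mean differences were -2.76 percentage points for first exons, 2.30 for skipped exons, 0.63 for alternative 3' splice sites, 0.61 for alternative 5' splice sites, -0.47 for retained introns, -0.21 for last exons and -0.09 for mutually exclusive exons. The groups did not overlap in any type, which chance gives for 33.3% of types. The 7 shares of a library add up to the whole, however, so the types are not independent. Every exact permutation p was 0.333, before and after adjustment over the 7 types. The first exon and skipped exon differences fell to -1.65 and 1.21 points without siSTAMBPL1 replicate 2, to -0.9351 and 1.2005 among events found in at least 2 libraries, and to -1.1416 and 1.1983 among events with Ensembl transcripts in both forms. Thinning of long-read transcripts turned the first exon difference to 0.41 points and the skipped exon difference to -0.05 points. The retained intron share stayed lower under thinning, at 8.69% and 8.69% in siNC and 8.40% and 8.07% in siSTAMBPL1. It did not among events with Ensembl transcripts in both forms, where the difference was 0.0038 points.

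**Figure D3:**
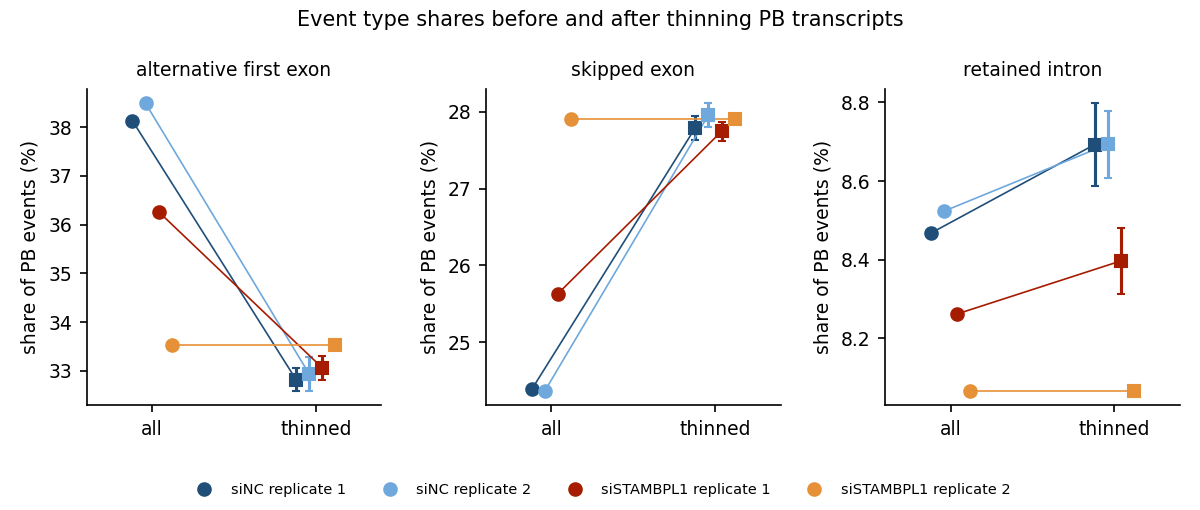
Share of 3 event types among events with a long-read (PB) transcript (%, vertical axes, which do not start at 0), before thinning (circles) and after thinning to 17584 transcripts (squares, mean of 20 draws, bars SD over draws), 1 colour per library. First exon and skipped exon shares of the 4 libraries draw together after thinning, while retained introns stay at 8.40% and 8.07% in siSTAMBPL1 against 8.69% in both siNC libraries.

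Most events were found in 1 library only. Of 287868 distinct events, 66.1% were found in 1 library and 16.03% in all 4. Of the 85625 events with Ensembl transcripts in both forms, 49.8% were found in all 4 and 22.6% in 1 library, against 84.5% in 1 library for the other events. Both siNC libraries and neither siSTAMBPL1 library listed 9915 events, and the reverse held for 3148 events. The pairs that mix the groups shared 6122, 3702, 6344 and 3754 events found in no other library, so the siSTAMBPL1 pair lay below each mixed pair. The Jaccard index was 0.325 for the siNC pair, 0.343 for the siSTAMBPL1 pair and 0.318 to 0.326 for the mixed pairs. With coordinates allowed to differ by up to 10 bases, it was 0.418, 0.430 and 0.399 to 0.418. Part of the events found in 1 library thus differ from others by a few bases only. After thinning to equal numbers of long-read transcripts, 3772 events were found in the siNC pair only and 3865 in the siSTAMBPL1 pair only. The mixed pairs had 3394, 3436, 3667 and 3429. These numbers come from a single draw, without a spread over draws. Only 3 splits of 4 libraries into pairs exist, so no p under 0.05 could be reached.

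Among genes with many siNC-only events, BAG6 (ENSG00000204463), a chaperone of protein quality control, had 86, of which 85 were first exon events. Its lists held 470, 535, 246 and 255 events. The adhesion receptor ADGRG1 had 71 siNC-only events, the lysosomal acid ceramidase ASAH1 45, the RNA-binding HNRNPUL1 39, the non-coding RNAs MIR4435-2HG and PVT1 38 and 35, the histone methyltransferase EHMT1 33, CIZ1 30, the transporter SLC43A3 30 and the transcription factor RFX5 29. In the other direction, PVT1 had 24 siSTAMBPL1-only events, the transcription factor ZEB2 24, the non-coding RNA ARLNC1 19, ASAH1 19, the calpain inhibitor CAST 17, the glycolytic enzyme PFKM 17, PAM 16, the deubiquitinase ATXN3 15, HNRNPK 15 and GPR108 14. PVT1 and ASAH1 thus stood among the leading 10 genes in both directions. The ranking uses raw numbers, which can be larger in genes with many events and in the larger siNC libraries. Mixed pairs were not ranked by gene for comparison. Events were matched on every coordinate, so a small difference in an exon end counts as another event.

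At the level of single genes, no gene passed the limma threshold in either direction among 9933 tested. The smallest adjusted p was 0.320, and 293 genes were higher and 434 lower at an unadjusted p under 0.05. That balance moved with the scaling and the unit: 186 were higher and 994 lower without scaling, 209 and 487 with upper quartile scaling, and 316 and 261 with thinned long-read transcripts. The other 2 splits of the libraries gave 370 and 323 genes at that level, against 727 for the real split. Only the real split also divides the libraries by their number of PB transcripts. A difference between the groups from any cause adds to the spread within the other splits and can lower their numbers. The larger number for the real split therefore does not show an effect of knockdown. The 4 libraries separated by group for 3779 genes (38.0%), where chance gives 33.3%: 2285 were higher and 1494 lower in siSTAMBPL1, the opposite balance to that at an unadjusted p under 0.05. Separation was scored after scaling for the library total, so an unchanged number can count as higher. HGD, with 6, 6, 6 and 6 events, counted as higher. The scaling thus adds to the higher genes, and 33.3% is not a firm chance level. Restricted to events with Ensembl transcripts in both forms, an alternative chosen after the data were seen, 4 genes were higher and 7 lower at an adjusted p under 0.05. Such events of a gene can be listed together through a single Ensembl transcript, which limits what these calls mean.

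Of the 12 genes with the largest log2 change towards siSTAMBPL1, 6 were listed at 0 in both siNC libraries. ARLNC1 (ENSG00000260896, chromosome 16, 80828735 to 80892596), a long non-coding RNA, had 0, 0, 40 and 23 events. ATXN3 (ENSG00000066427, chromosome 14, 92044775 to 92106582), a deubiquitinase that carries a polyglutamine tract, had 0, 0, 21 and 17. CCDC120 had 0, 0, 21 and 15 events, the carbohydrate kinase FGGY 0, 0, 17 and 10, the ERBB ligand NRG1 0, 0, 15 and 11, YPEL4 0, 0, 12 and 11, and the dynein heavy chain DNAH14 0, 1, 18 and 13. The remaining 5 genes varied within siNC: the recombination protein RAD52 had 0, 10, 17 and 37 events, OR2A1-AS1 7, 0, 20 and 18, SLC12A2-DT 0, 27, 37 and 25, FAM156A 0, 11, 18 and 19, and ST7L 0, 20, 33 and 18. SLC12A2-DT and ST7L lay above both siNC libraries in siSTAMBPL1 replicate 2 only after scaling for the library total, and the ST7L difference turned to -0.03 among events with a long-read transcript. Limma adjusted p-values were 0.320 for ARLNC1 and ATXN3 and 0.765 for ST7L. PB transcripts were few: those in ATXN3 events numbered 0, 0, 1 and 0, and none was listed for NRG1 in any library. Events without a PB transcript were listed through Ensembl transcripts, whose number found in a library is not known.

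In the other direction, 11 of 12 genes were listed at 0 in both siSTAMBPL1 libraries. In both directions the rule takes the largest log2 changes, which favours genes at 0 in a group. Zeros were also more common in siSTAMBPL1 in general: of all 9933 tested genes, 585, 569, 844 and 1426 had no event. ARHGAP27 had 43, 16, 0 and 0 events. CMC2 (ENSG00000103121, chromosome 16, 80966448 to 81006885), a factor of cytochrome c oxidase assembly, had 22, 17, 0 and 0. MBNL1 (ENSG00000152601, chromosome 3, 152243632 to 152465780), a regulator of alternative splicing, had 17, 15, 0 and 0. MIR924HG had 15, 23, 0 and 0 events, the anaphase-promoting complex subunit ANAPC10 9, 33, 0 and 0, the adaptor GRB7 11, 25, 0 and 0, COMMD4 18, 15, 0 and 0, BRME1 14, 15, 0 and 0, the protein phosphatase subunit PPP1R3E 13, 14, 0 and 0, the adhesion molecule MCAM 13, 13, 0 and 0, and COBLL1 9, 18, 0 and 0. The guanylate kinase GUK1 had 60, 51, 15 and 0 events. Limma adjusted p-values were 0.372 for ARHGAP27, 0.320 for CMC2 and MBNL1 and 0.728 for GUK1. Among events with Ensembl transcripts in both forms, ARLNC1, ATXN3, NRG1, YPEL4, CMC2, COMMD4, MBNL1 and MCAM passed, with limma adjusted p between 0.0315 and 0.0486. A single Ensembl transcript, once found, lists all such events that it belongs to. Numbers in replicates can therefore agree by construction, as for MCAM, which had no PB transcript in any library. The spread within groups is then understated, and these calls amount to listed against not listed.

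**Figure D4:**
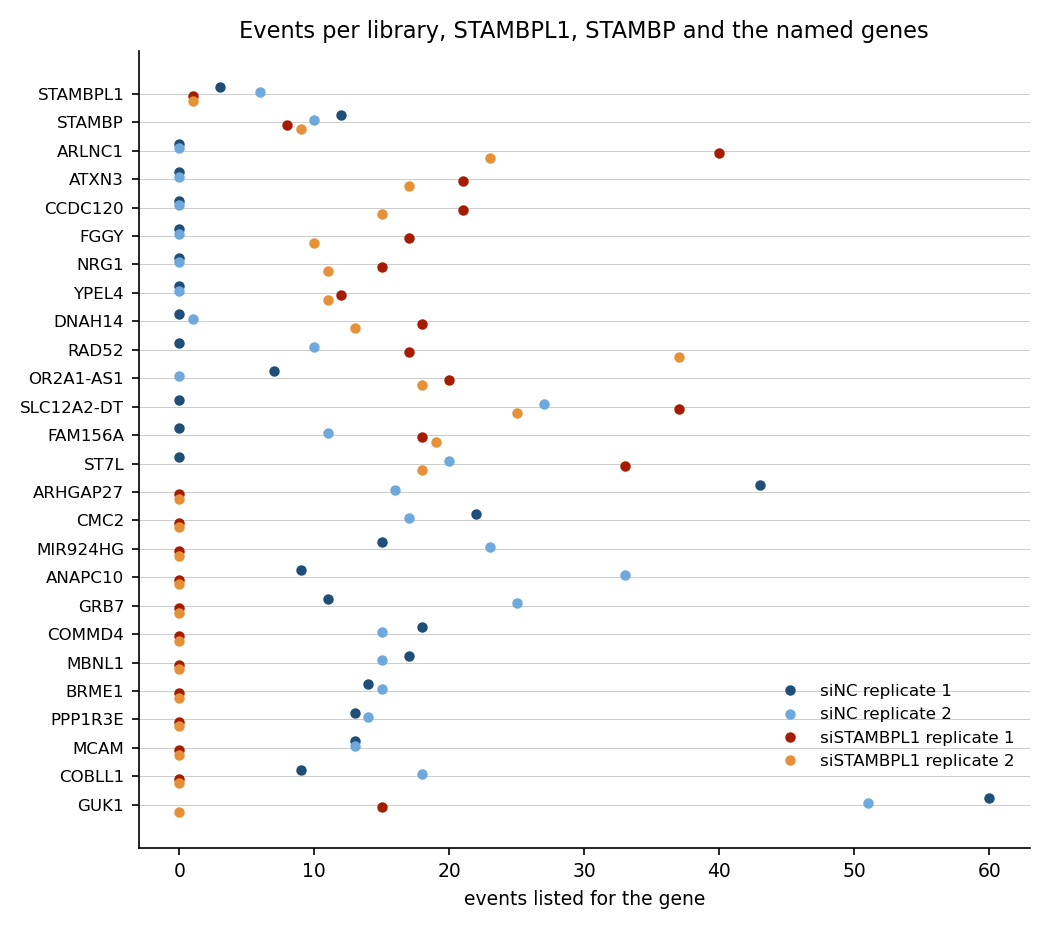
Events listed per gene (horizontal axis) for STAMBPL1, STAMBP and the 24 genes with the largest log2 change, with 1 point per library. Of the 12 lower genes, 11 lie at 0 in both siSTAMBPL1 libraries, and GUK1 has 60, 51, 15 and 0 events. The genes were picked for the size of their change, which favours zeros.

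Of 28 gene lists fixed in advance, 27 had enough genes to test, and 1 passed. Of the tested cytosolic ribosomal protein genes, 39 of 55 lay below 0 and 16 above, with a median log2 change of -0.75 (camera adjusted p = 0.0134). The call was lost with an estimated correlation (adjusted p = 0.827) and with fry (adjusted p = 0.238). No member passed over all genes, and 0 passed when adjusted over the list alone. RPS15A had 8, 11, 0 and 0 events, RPL21 had 5, 5, 0 and 0, and RPL34 had 4, 4, 0 and 0. RPSA was higher, with a log2 change of 1.19 (SE 0.309). Among the 55 genes, 0, 0, 6 and 21 had no event in the 4 libraries, so siSTAMBPL1 replicate 2 carried most of the shift. Without it the median was -0.11 and the adjusted p 0.408; without siNC replicate 1 or 2 the adjusted p was 0.522 or 0.514. Without siSTAMBPL1 replicate 1 the list passed (adjusted p = 0.000132).

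Genes of RNA processing did not pass camera as lists. Of 42 core spliceosome genes 26 lay below 0 (median -0.22, camera adjusted p = 0.338). Among them SF3B3 had a log2 change of -0.99 (SE 0.292) and U2AF2, which binds the polypyrimidine tract, -1.23 (SE 0.391), while USP39 had 0.65 (SE 0.215) and SART1 1.21 (SE 0.423). Of 23 hnRNP genes 14 lay below 0 (median -0.27, adjusted p = 0.522). HNRNPUL1 had a change of -1.04 and PTBP1, a repressor of exon inclusion, -1.22. Of 20 SR protein genes 14 lay above 0 (median 0.22, adjusted p = 0.672), with TRA2A at 0.87 and SRSF1 at -1.49. Other splicing regulators had a median of -0.05 over 36 genes (adjusted p = 0.672), with MBNL3 at -0.96, RBFOX2 at -0.93 and DDX5 at 0.70. In this list MBNL1 passed when adjusted over the list alone, the only such gene of it. Nonsense-mediated decay genes had a median of -0.13 over 16 genes (adjusted p = 0.672), and the helicase UPF1 had 7 and 4 events in siNC and none in siSTAMBPL1.

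The ubiquitin lists did not pass camera either. The mixed test of fry, which asks whether members change in either direction and compares a list with no other genes, gave an adjusted p of 6.63e-06 for other deubiquitinases and 0.00379 for endosomal sorting genes. It also gave 0.00742 for the core spliceosome, 0.00225 for other splicing regulators, 0.0107 for ribosomal proteins and 0.0139 for PI3K, mTOR and growth factor receptors. At an unadjusted limma p under 0.05, 3 of the other deubiquitinases were higher and 1 lower, and 1 endosomal sorting gene was higher and 0 lower. A few genes that go between 0 and several events can thus give a small mixed p. The groups also differ in their number of PB transcripts. Deubiquitinases other than STAMBP and STAMBPL1 had 20 genes above and 19 below 0 (median 0.03, camera adjusted p = 0.672). ATXN3 passed when adjusted over the list alone. MYSM1, a histone deubiquitinase, had 4, 5, 0 and 0 events, while USP21 had a log2 change of 0.99 and USP39, also a spliceosome gene, 0.65. Endosomal sorting genes had 18 of 26 above 0 (median 0.25, adjusted p = 0.522), with MVB12B at 0, 0, 3 and 4 events, STAMBPL1 itself at a log2 change of -1.14 and CHMP7 at 0.64. E1, E2 and E3 enzymes had a median of 0.11 over 45 genes (adjusted p = 0.672), with KEAP1, an adaptor of NRF2 degradation, at -0.99 and CUL4A at 0.90. Proteasome genes had a median of -0.02 over 30 genes (adjusted p = 0.939), with the camera direction up.

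Among growth and stress lists, cell cycle genes had 26 of 41 below 0 (median -0.21, camera adjusted p = 0.236). MCM3, a subunit of the replicative helicase, had a log2 change of -1.05, the cyclin CCND1 had 2, 8, 0 and 0 events, the transcription factor E2F1 had 2, 3, 0 and 0, and PLK1, a mitotic kinase, had a log2 change of -0.84. The cell cycle list passed with long-read transcripts per gene in place of events (median -0.61, adjusted p = 0.00135) and without scaling (adjusted p = 0.0418). Autophagy and lysosome genes had 27 of 39 above 0 (median 0.25, adjusted p = 0.332), with the kinase ULK1, at 1, 1, 3 and 2 events, changed by 1.04 and CTSA, a lysosomal protease, by 0.77. That list passed only without siSTAMBPL1 replicate 2 (adjusted p = 0.0357). Medians and adjusted p were 0.11 and 0.672 for apoptosis, -0.01 and 0.939 for p53 and DNA damage, 0.07 and 0.672 for PI3K, mTOR and growth factor receptors, 0.10 and 0.672 for NF-kB and TNF signalling, -0.18 and 0.939 for Wnt signalling, 0.13 and 0.672 for endoplasmic reticulum stress, and 0.18 and 0.939 for interferon and RNA sensing. For PI3K, mTOR and growth factor receptors the mean was negative (-0.14), as was the camera direction, and HRAS had 11, 5, 0 and 0 events. For Wnt signalling the mean was -0.03 and the camera direction was up. For interferon genes the mean was -0.09, with the camera direction up.

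Among metabolic and structural lists, cholesterol and lipid synthesis had a median of -0.11 over 39 genes (camera adjusted p = 0.672). SREBF2, which encodes a transcription factor of cholesterol synthesis, had a log2 change of -2.19 (SE 0.277) and was the 1 gene of the list that passed when adjusted over the list alone. SREBF1 had a change of -1.26. Translation factors had a median of -0.07 (adjusted p = 0.672), glycolysis and hypoxia 0.12 (0.939), oxidative phosphorylation 0.08 (0.839), actin cytoskeleton 0.09 (0.939) and epithelial-mesenchymal and adhesion genes 0.17 (0.939). Means of the glycolysis and oxidative phosphorylation lists were -0.01, with the camera direction up for both. Of these genes, ATP5F1A, an ATP synthase subunit, had a change of 1.00, EGLN1, an oxygen sensor, -1.18 and KRT8, a keratin of simple epithelia, 1.30.

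**Figure D5:**
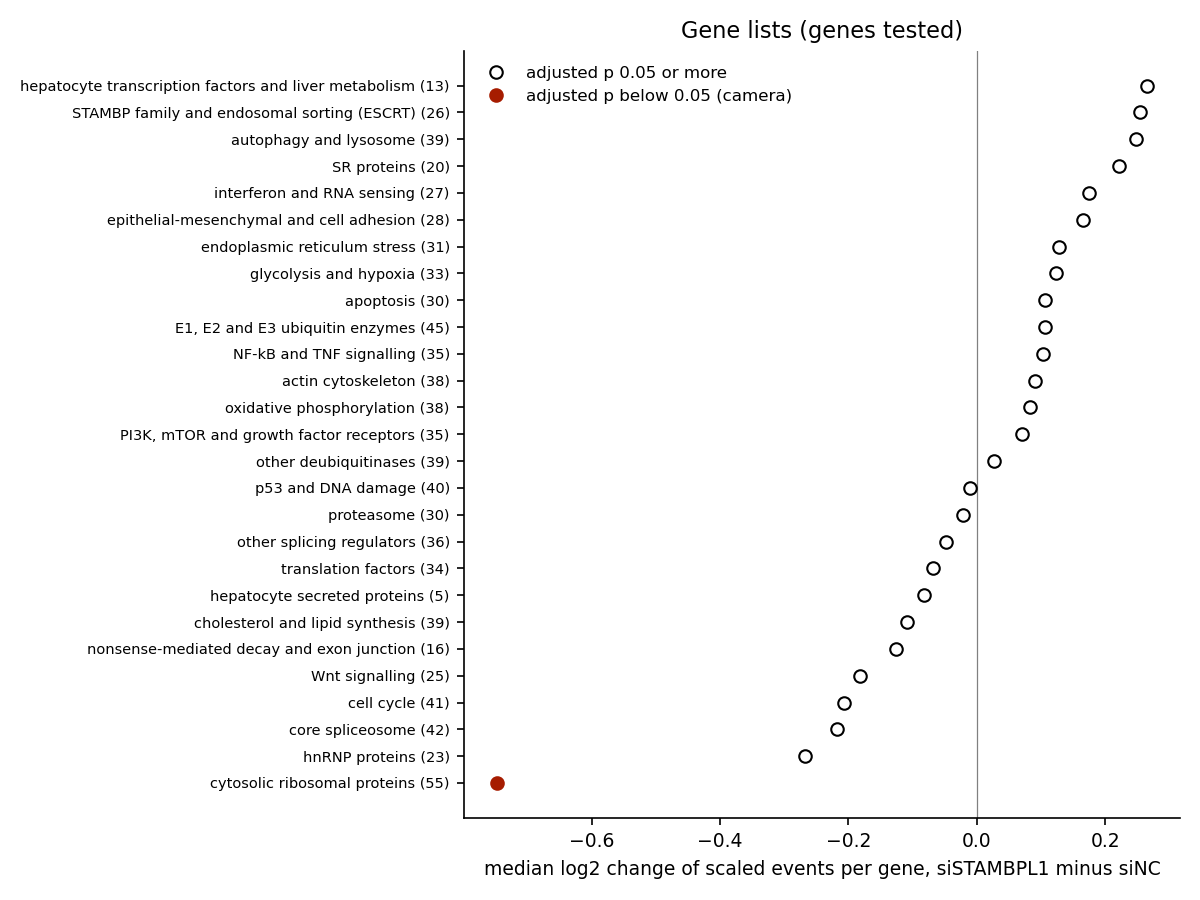
Median log2 change of scaled events per gene (siSTAMBPL1 minus siNC, horizontal axis) for the 27 tested lists, with the number of tested genes in brackets. The filled point, cytosolic ribosomal proteins at -0.75, is the only list with a camera adjusted p under 0.05.

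Hepatocyte lists were sparsely represented in all 4 libraries. Of 50 genes for hepatocyte secreted proteins 5 had an event, and of 42 hepatocyte transcription factor and metabolism genes 14, against 43 of 50 core spliceosome genes. HNF4A, a hepatocyte transcription factor, had 8, 6, 0 and 4 events, and CPS1, an enzyme of the urea cycle, had 8, 1, 7 and 5. The secreted list had a median of -0.08 over 5 genes (camera adjusted p = 0.939, direction up), with a mean of 0.13, and the transcription factor and metabolism list 0.27 over 13 genes (adjusted p = 0.731, direction up), with a mean of -0.05. Of 36 markers of other cell types 5 had an event, too few matched genes to test as a list: KRT7 had 27, 38, 19 and 9 events, TUBB3 31, 37, 22 and 31, PDGFRB 0, 4, 5 and 5, CD68 3, 2, 2 and 2, and VWF 3, 0, 0 and 0.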

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

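Alternatives that used long-read transcripts, seen forms, Ensembl transcripts in both forms or events without first and last exons, and leaving out libraries for shared events, were chosen after the data were seen. The ratio of events stayed under 1 in every alternative, from 0.599 with both forms seen to 0.995 with thinned long-read transcripts. With thinned transcripts the differences in type shares were 0.4139 points for first exons, 0.1628 for last exons, -0.0498 for skipped exons, -0.1632 for alternative 3' splice sites and 0.0838 for mutually exclusive exons, each opposite in sign to the reported one. Counted as genes with the type, they were -0.294 for skipped exons, -2.3122 for 3' and -2.3068 for 5' splice sites. Retained introns gave 0.0038 among events with Ensembl transcripts in both forms, and mutually exclusive exons 0.0036 among events with a long-read transcript. Beyond the thinning, a cause was tested for retained introns alone, among the other observations.

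Events in the siNC pair only numbered 5160 with events thinned and 3772 with long-read transcripts thinned, and 14240 to 69812 with 1 library left out. Events in the siSTAMBPL1 pair only numbered 7900 with events thinned, and 5583 to 46624 with 1 library left out. Leaving a library out weakens the condition itself, so these last numbers must grow. Thinning of events draws from the larger libraries at random and so lowers their overlap by construction.

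Calls at the gene level were 0 in each direction under every alternative except events with Ensembl transcripts in both forms, with 4 higher and 7 lower. The replicate numbers did not pair the libraries (correlation of deviations 0.019). With the replicate block 0 genes were higher, 0 lower and 557 under an unadjusted p of 0.05. Without scaling the median log2 change of all genes was -0.29, against 0.05. STAMBPL1 stayed negative in each alternative that fitted it, at -0.5994 with pseudocount 4, -0.7368 without siNC replicate 2 and -1.9149 with long-read events, against -1.1361. It was below the filter, and so not fitted, with a filter of 20 events, both forms seen, thinned transcripts, no first or last exons, and Ensembl transcripts in both forms. STAMBP was -0.334 without scaling, -0.0428 with upper quartile scaling, -1.1947 with long-read events, -0.7508 with long-read transcripts per gene, -1.6242 with thinned transcripts and -0.0075 with Ensembl transcripts in both forms, and lay between -0.1922 and 0.2708 with 1 library left out. ST7L was -0.0306 with long-read events and -0.1672 with thinned transcripts. No STAMBP or ST7L value passed.

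The ribosomal list lost its call at the same median of -0.748 with an estimated correlation (0 lists lower) and with fry (0 lists lower). It lost it at -0.2193 with long-read transcripts per gene, where 13 genes were tested and the cell cycle list passed at -0.6058, and at -1.0575 with thinned transcripts, where 26 genes were tested and 0 lists were lower. With 1 library left out it lay between -0.6433 and -0.1061, with 0 to 1 lists lower and 0 to 1 higher. With the replicate block it passed (adjusted p = 0.00692). Without scaling 2 lists were lower, the cell cycle list at -0.5483. No cause was tested beyond those weighed among the other observations. The alternatives fixed in advance for single events (minimum reads, another test, block, left-out libraries) were not run because the files hold no quantity per event.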

Other observations

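All tests below were chosen after the patterns had been seen. For 3 of them (the retained intron share of events found in 1 siNC library, the isoform-matched lists and the tissue panels), what each explanation predicts was written down before their own values were computed.

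Changes of form were looked for among the 46136 events found in all 4 libraries. In 9162 of them the forms found were known for every library. Between the groups, 12 events had 1 form in both libraries of 1 group and the other form in both libraries of the other, against 10 and 9 events in the other 2 splits. They included a skipped exon event in SYVN1, which encodes a ubiquitin ligase of the endoplasmic reticulum, a skipped exon event in STRN3, an alternative first exon in ASAH1 and a retained intron in OGFOD2, named after their values were seen. With 3 splits, no share under 0.05 can be reached. Both forms in siNC and 1 form in siSTAMBPL1 were found for 277 events, and the reverse for 75. The other 2 splits gave 164 and 100, and 100 and 192, and fewer transcripts in siSTAMBPL1 would give this direction by themselves.

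The lower number of events and the shifted mix of types in siSTAMBPL1 may reflect the lower number of long-read transcripts. With equal numbers of transcripts the first exon difference went from -3.41 to 0.4139 points and the skipped exon difference from 2.40 to -0.0498 points. Both differences thus go with the number of PB transcripts. Whether lower depth or the knockdown lowered that number cannot be told apart, as read numbers are not given. Random thinning also only approximates a lower depth. For retained introns the difference was -0.4619 ± 0.0753 points (SD over draws) after thinning and -0.33 before. Random loss of transcripts, as drawn here, thus did not remove it. That SD covers the draws only and not the spread between libraries. The exact permutation p of the thinned shares was 0.333, the smallest possible. For loss of the rarer transcripts, events of a siNC library that its partner did not list were compared with shared ones. They differed by -3.668 points in retained intron share for siNC replicate 1 and -3.484 for replicate 2, so losing them would raise the share. Among events with Ensembl transcripts in both forms the differences were -1.449 and -1.96. This speaks against such a loss only as far as unlisted means rare. Events that differ in any coordinate also count as unlisted, whatever their abundance. After thinning the share was 8.40% in siSTAMBPL1 replicate 1 and 8.07% in replicate 2, against 8.69% in both siNC libraries. Replicate 2 thus did not carry the difference alone. Knockdown, RNA quality, chance variation between libraries and a lower depth by another route remain open. The difference was absent among events with Ensembl transcripts in both forms.

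Few hepatocyte genes had an event in these lists. Of 92 such genes 19 had one, and 64 of the other 73 had no event coordinate of any gene inside their span. Few annotated isoforms are argued against: 0 of 10000 random lists with the same numbers of RefSeq transcripts had as few, and their median was 42. A second panel of 20 liver genes, written before its result was computed, had 5.0% listed, against 33.33% for squamous epithelium, 20.0% for intestine and neural, 13.33% for kidney tubule, blood, and fibroblast and endothelium, 6.67% for muscle, and all 15 housekeeping genes. That is what RNA of cells that make little use of liver genes would give, as a hypothesis only: HNF4A, CPS1 and C3 did have events, and genes left out of the lists analysed here would look alike. ALB, AFP, APOB, TF, SERPINA1 and F11, named after their values were seen, had no event, and no event position lay inside them, although SERPINA1 and F11 have 16 RefSeq transcripts each. Whether the material was what the Huh7 label says is left open by these lists.

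A low mean level alone did not give the lower ribosomal protein genes: the list median lay at percentile 0 of 10000 random lists matched on mean level. Random lists hold unrelated genes and so lack the correlation within a family. With an estimated correlation the camera adjusted p of the ribosomal list was 0.827. Low percentiles were not particular to it: core spliceosome stood at 0.72, hnRNP proteins at 0.8, cell cycle at 1.0, cholesterol and lipid synthesis at 4.46 and Wnt signalling at 4.94, none of which passed camera. A single library may carry most of it. Without siSTAMBPL1 replicate 2, the library with the fewest events, the median went from -0.75 to -0.1061, and 38.18% of the list's genes had no event in that library, against 14.36% of all genes. Whether transcripts of this short, pseudogene-rich family were harder to detect there, or were fewer, stays open.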
